A study of Danio rerio with 4 samples.

How the data were processed

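Liver RNA of zebrafish was measured on 4 two-colour Agilent oligonucleotide arrays. Per the labels, the 4 RNAs were 2 biological replicates of a control without cadmium (replicates 2 and 3) and 2 of a 5 µM cadmium treatment (replicates 1 and 2), all at day 4. The RNAs formed a loop in which each was labelled once with Cy5 and once with Cy3. Each array therefore set 1 control RNA against 1 cadmium RNA, and each RNA was on 2 arrays. The unit of the dose is the one in the series' design text, and a label of the samples writes another unit beside the same number.

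The deposited values were log2 ratios of the dyes, 1 per probe and array, for 43603 probes with 0 missing values. The processing notes of the submitters name limma without a version, and the labels name version 5.7 of the Agilent two-colour labelling protocol. Background correction, normalization and filters are not given in the sources used here, and no scanner values were used. The log base was taken as 2 because a largest value of 6.14 would lie beyond a scanner's range in base 10. Each column's median lay near 0 (-7.46e-05, -0.000451, 0.000711 and 0.00373 on arrays 1 to 4), so the deposited log2 ratios appear centred, by a method that stays unknown. The direction of the ratio is not stated either. It was taken as Cy5 over Cy3, which is likely because this is limma's convention and the titles of the arrays name the Cy5 RNA first. Under the opposite direction every signed value would change its sign, with sizes and p-values kept. Arrays of one dye orientation correlated at -0.04 (arrays 1 and 3) and -0.22 (arrays 2 and 4) across probes.

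The ratios of the 4 arrays were solved, probe by probe, for 3 differences between RNAs and 1 dye effect. This gave 4 RNA-level log2 values per probe, relative to their mean. Cadmium and control were compared 2 RNAs against 2 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The RNA and not the array was the unit, because arrays that share an RNA are not independent. In this loop, array noise enters the difference between RNAs of one group with more variance than the difference between group means, so where it outweighs the differences between RNAs the test gives too few calls. Errors printed after a log2 difference are moderated standard errors (SE) with 2 RNAs per group, and they carry 2 residual degrees of freedom plus a prior of 2.17 for probes and 1.91 for genes. The labels call the replicates biological but do not say whether an RNA came from 1 fish or a pool, so p-values measure the spread between these RNAs. The number of arrays limits the precision, and the files give no signal level or background per spot.

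Probes were named through the platform's annotation table. Of the probes, 23717 carried 1 gene symbol, 0 carried several and 19886 are unnamed here. The gene identifiers of 23534 probes were found in the RefSeq gene table, 183 were not, and 0 symbols changed by it. A gene's value was the mean over its probes, for 15554 genes. Of 6104 genes with more than 1 probe, 3539 had all probes on one side of 0.

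Before the data were examined, 32 gene lists were written, covering responses that fit cadmium and liver and markers of other tissues that a dissection could hold. Older symbols were matched through synonyms. A synonym that led from a metallothionein to a melatonin receptor was left out after the match was inspected. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (all limma), adjusted over the 32 lists, each with at least 5 measured genes. For the glycolysis and clock lists, the estimated correlation (-0.0037 and -0.031) lay below the preset one. Their unadjusted camera p still rose, from 0.0218 to 0.114 and from 0.0249 to 0.126. Camera at an estimated correlation draws on the 2 residual degrees of freedom, whereas the preset setting draws on the number of genes. A call lost with the estimated correlation therefore cannot be put down to gene correlation alone. With 2 RNAs per group that setting has little power, and it called 0 of the 32 lists.

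The genes to be named were fixed by rule at the same time. The first part takes genes past the threshold with all 4 arrays on one side, 12 per direction. Where fewer pass, it is filled to 12 by the largest moderated t among genes with all 4 arrays on one side and a log2 difference of at least 0.5 in size. The second part takes the 4 members of each list with the largest moderated t in size. The third part takes mt2, mtbl, mtf1, hmox1a, hsp70l, cyp1a, vtg1 and slc30a1. Of these, mt2 and vtg1 were not found under that symbol, and slc30a1 was found as slc30a1a. Clone and locus names come after the others.

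The method was tested on simulated data for 43603 probes, with variances drawn from the fitted prior and 50 changed probes per size. Array noise of a fixed size, not fitted to these data, was added. At a log2 size of 0.5 and of 1, 0% were recovered, at 2 it was 86% and at 3 it was 98%. Among 43403 unchanged probes, 8 were called with RNAs as units and 44 with arrays as units. An unadjusted limma p under 0.05 was reached by 4.27% of them with RNAs as units, against 1.52% of the real probes. The simulated noise thus differs from the real one, and the recovery rates are a rough guide. A gene list shifted on purpose was recovered with 0 other lists called. Probes were drawn independently there, whereas estimated correlations in the real lists reached 0.70 (oxidative phosphorylation). The simulation therefore does not show how often lists of correlated genes are called falsely. The alternatives tried were arrays as units with and without a dye coefficient, centring, scaling and quantile normalization of the arrays, a robust variance prior, filters on probes, a threshold on size (treat), the median over probes, and leaving out each RNA or array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.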

Results

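The series tested how the zebrafish liver transcriptome differs between fish exposed to 5 µM cadmium and controls, as a trial experiment for a custom array. It comprised 4 arrays with 2 control and 2 cadmium RNAs from day 4. Array 1 paired control replicate 2 with cadmium replicate 1, array 2 cadmium replicate 1 with control replicate 3, array 3 control replicate 3 with cadmium replicate 2, and array 4 cadmium replicate 2 with control replicate 2. The standard deviation of the log2 ratios over 43603 probes was 0.198, 0.230, 0.388 and 0.353 on arrays 1 to 4, so both arrays that carried cadmium replicate 2 had the wider spread.

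Of the genes named by the rule fixed in advance, which ranks by moderated t, hamp and chia.6 had the lowest values in the cadmium livers relative to control. Signs here and throughout take the deposited ratio as Cy5 over Cy3, the likely direction, and under the opposite reading each sign would turn. The log2 difference of hamp (Entrez Gene 402837), which encodes the iron-regulating liver hormone hepcidin, was -2.82 ± 0.23 (SE, 2 RNAs per group), with array values between -3.17 and -2.32. For chia.6 (Entrez Gene 322420), an acidic chitinase, it was -1.83 ± 0.09. The AP-1 transcription factor gene junba was at -1.21 ± 0.12 and plin2, which encodes a lipid droplet coat protein, at -0.997 ± 0.101. Also lower on all 4 arrays were the complement genes cfhl3 (-0.87) and c4b (-0.72), the mitochondrial arginase gene arg2 (-0.79), the aminopeptidase gene enpep (-0.85), the epithelial ETS factor gene elf3 (-0.78), the interferon-inducible GTPase gene gbp1 (-0.72), the activin subunit gene inhbab (-0.70) and ginm1 (-0.61). For ginm1, arrays 1 and 3 gave only -0.01 and -0.23 against -1.06 and -1.14 on arrays 2 and 4, with a dye effect of -0.49.

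The 12 genes named on the higher side included several enzymes of amino acid metabolism. The log2 difference was 1.02 ± 0.10 for mat1a (Entrez Gene 334195), which makes S-adenosylmethionine in liver, and 0.90 ± 0.12 for tdo2b, which opens tryptophan breakdown. It was 1.36 ± 0.21 for the aromatic amino acid transporter gene slc16a10 and 0.57 ± 0.09 for aldh7a1, an enzyme of lysine breakdown. The clock output factor tefa (Entrez Gene 30674) was at 1.02 ± 0.10, with its 3 probes on one side. The mitochondrial genes grpel1, a cofactor of the organelle's Hsp70 chaperone, and phb, a prohibitin, were at 0.81 and 0.74. The remaining genes of this group were aacs (0.96), ddah1 (0.86), ppdpfa (0.66), lars1b (0.63) and odc1 (0.63), the last the first enzyme of polyamine synthesis.

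**Figure D1:**
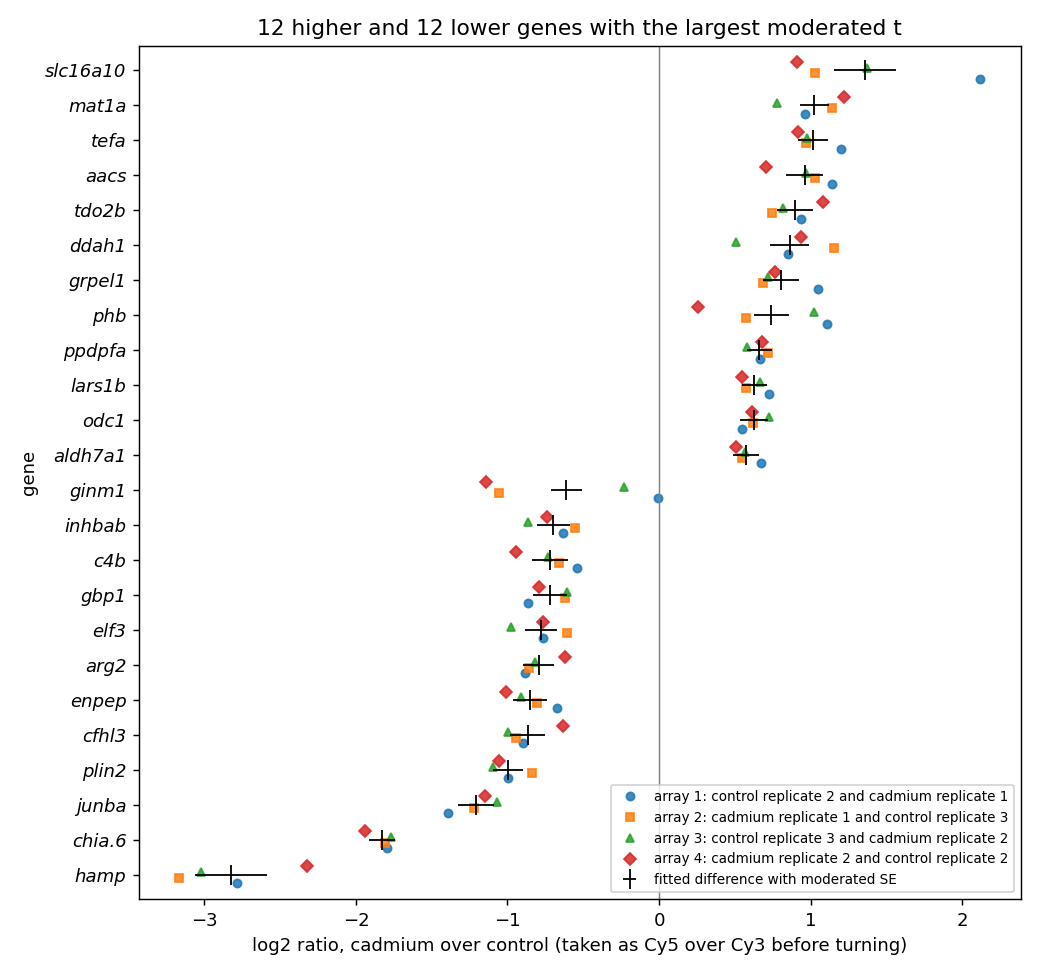
Log2 ratios of cadmium over control (horizontal axis) for the 12 higher and 12 lower genes with the largest moderated t (vertical axis), with 1 symbol per array and a black bar for the fitted difference with its moderated standard error. The 4 arrays of hamp lie between -3.17 and -2.32, and those of chia.6 near -1.83, while none of the 24 genes passed the adjusted threshold.

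None of these 24 genes passed the test. In limma 0 of 15554 genes and 0 of 43603 probes had an adjusted p under 0.05, the smallest being 0.567 (chia.6) and 0.853. At an unadjusted p under 0.05 there were 314 genes (2.02% of those tested, 167 higher and 147 lower) and 662 probes (1.52%). A total of 269 genes had all 4 arrays on one side and a size of at least 0.5, 101 higher and 168 lower. Of all genes, 21.8% had both cadmium RNAs on one side of both control RNAs, where chance gives 33.3% for 2 against 2 if only the RNAs vary, and less if array noise adds to it. Groupings that mixed a control with a cadmium RNA on each side gave 731 and 728 genes at an unadjusted p under 0.05 against the 314, but they carry more array noise in this loop, and 3 groupings cannot give a share under 0.05. With the 4 arrays as units and no dye term, chia.6 and hamp were the 2 genes called. The count of 0 depends on cadmium replicate 1, since without it 1456 genes and 2523 probes were called, with cadmium replicate 2 alone standing for the treatment and assumed to vary like the controls. Leaving out 1 RNA moved 0 of these 24 genes, whose ranking favours a small spread, by over 1.5 times, but 79 of all 145 genes named by the rule, 55 of them without cadmium replicate 2, 47 without cadmium replicate 1, 30 without control replicate 2 and 24 without control replicate 3.

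The metal and stress genes chosen in advance lay near 0 or below. The metallothionein-like gene mtbl was at 0.06 ± 0.12, the heat shock gene hsp70l at 0.04 ± 0.12 and the cytochrome P450 gene cyp1a at 0.02 ± 0.11, each turning its sign when 1 RNA was left out. The heme oxygenase gene hmox1a was at -0.74 ± 0.25, with the mean of its probes lower on all 4 arrays. Its probes were at -1.03 and -0.45, the latter at 0.13 on array 4. Without control replicate 3, hmox1a was at -0.48. The metal-responsive transcription factor gene mtf1 was at -0.42 ± 0.48, and at 0.22 without cadmium replicate 2. A metallothionein probe set annotated as mt, chosen after its value was seen, was at 0.15 ± 0.20. Of the 12 measured genes of metal handling 6 were higher and 6 lower, among them the zinc transporter genes slc39a3 (-0.58 ± 0.30) and slc30a1a (-0.27 ± 0.20) and the ceruloplasmin gene cp (-0.18 ± 0.20). Without cadmium replicate 2, slc39a3 was at -0.17 and slc30a1a at -0.008, and without control replicate 3 cp was at 0.08. The list was not called by camera (adjusted p = 0.188), but it was called down without cadmium replicate 1 (0.0332) and turned up, uncalled, without cadmium replicate 2 (0.812).

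Heat shock genes were higher in 25 of 38 and the list was not called (adjusted p = 0.292). Its leading members included the mitochondrial chaperone genes hspd1 (0.43 ± 0.09), hspa9 (0.38 ± 0.10) and hspe1 (0.71 ± 0.24), beside hsf2 (0.67 ± 0.23). The probes of hspd1 were at 0.84 and 0.01, and those of hspa9 lay between -0.07 and 0.68. Without cadmium replicate 1 hspe1 was at 0.44, and without control replicate 2 hsf2 was at 0.36. Of 43 genes of oxidative stress and glutathione 22 were higher (adjusted p = 0.626), with sod2 at 0.44, pgd at 0.49, gstp1.2 at 0.42 and gpx4a at -0.48. That list was called down without cadmium replicate 1 (0.0396). Endoplasmic reticulum stress genes were higher in 25 of 36 (adjusted p = 0.951), with xbp1 at 0.69, asns at 0.32, atf4b at -0.40 and atf3 at -0.55. This list was called down without cadmium replicate 2 (0.000273) and stood up, uncalled, without cadmium replicate 1 (0.0572). For it and for the oxidative stress list the median was above 0 and the direction of camera was down. Among 22 genes of the p53 and DNA damage list 10 were higher (adjusted p = 0.271), with ddb2 at 0.65, gadd45ga at -0.87, sesn3 at -0.80 and ccng1 at -0.29. Of these, ddb2 was at 0.39 without control replicate 2, gadd45ga at -0.50 without cadmium replicate 1 and sesn3 at -0.42 without cadmium replicate 2. In the iron and haem list 13 of 23 genes were higher (adjusted p = 0.764). Beside hamp these were led by the transferrin receptor gene tfr1b (0.55 ± 0.13), the hemopexin gene hpxa (0.48 ± 0.14) and slc40a1 (0.35 ± 0.11), which encodes the iron exporter that hepcidin acts on. The mean of this list was negative and its median positive. Adjusted over the list alone, 1 iron gene passed (hamp) against 0 over all genes.

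Immediate early and inflammatory genes were lower in the cadmium livers in 23 of 32 measured cases, 14 of them on all 4 arrays. After junba the leading members were nfkbiaa (-0.90 ± 0.19), an inhibitor of NF-kB, and the transcription factor genes cebpd (-0.68 ± 0.14) and cebpb (-0.66 ± 0.15). Camera called the list down at the preset correlation (adjusted p = 1.83e-09), and the call was lost with adjusted p = 0.575 with an estimated correlation. Without 1 RNA at a time the adjusted p at the preset correlation lay between 1.34e-10 and 9.48e-05. Adjusted over the list alone, 1 gene passed (junba).

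Glucocorticoid-responsive genes were lower in 15 of 18 cases, with igfbp1a at -1.42 ± 0.25, the cytokine signalling inhibitor gene socs3a at -1.06 ± 0.28 and the kinase gene sgk1 at -0.38 ± 0.12. The list shares 2 genes with the immediate early list. Its call was down (adjusted p = 4.40e-06, and adjusted p = 0.575 with an estimated correlation), and 0 genes passed when adjusted over the list alone. Acute phase and complement genes were lower in 28 of 38 cases, with c9 at -0.25 ± 0.08, c3a.2 at -0.29 ± 0.10 and hpxa on the other side. That list was called down (adjusted p = 1.15e-05, and adjusted p = 0.575 with an estimated correlation), and 1 gene, hamp, passed when adjusted over the list alone. Without cadmium replicate 2 its adjusted p was 0.123.

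Cholesterol synthesis genes were higher in 19 of 23 cases. The largest moderated t belonged to lss (0.49 ± 0.11), cyp51 (0.53 ± 0.14), ebp (0.70 ± 0.23) and hsd17b7 (0.39 ± 0.16), all enzymes of the steps from squalene epoxide to cholesterol. Without cadmium replicate 2, ebp was at 0.43 and hsd17b7 at 0.25. Relative to the mean of the 4 RNAs, the list median was 0.01 in cadmium replicate 1 and 0.29 in cadmium replicate 2. Genes of earlier steps, picked out after their values were seen, differed among themselves. The gene of the rate-limiting enzyme, hmgcra, was at 0.09 ± 0.09 and hmgcs1 at 0.15 ± 0.25. In contrast, acat2 was at 0.67 ± 0.31 and mvda at 0.58 ± 0.28, both higher on all 4 arrays. The list was called up (adjusted p = 0.000697, and adjusted p = 0.575 with an estimated correlation). Genes of fatty acid and triglyceride synthesis were lower in 15 of 25 cases. They included acaca, the acetyl-CoA carboxylase gene, at 1.25 ± 0.38 on the higher side, and agpat3 (-0.44) and lpla (-0.41) on the lower. Without cadmium replicate 1 acaca was at 0.75. Without cadmium replicate 2 acaca was at 1.75, agpat3 at -0.28 and lpla at -0.25. The call was down (adjusted p = 0.0144, and adjusted p = 0.592 with an estimated correlation), plin2 passed when adjusted over the list alone, and the adjusted p was 0.132 without control replicate 2. Fatty acid oxidation genes were lower in 25 of 34 cases, with acox3 at -0.21, acadvl at -0.69, acads at -0.41 and cpt1b at -1.08. Without cadmium replicate 2, acadvl, acads and cpt1b were at -0.35, -0.23 and -0.45, without cadmium replicate 1 cpt1b was at -1.72, and without control replicate 2 acads was at -0.28. The list was called down (adjusted p = 0.000220, and adjusted p = 0.592 with an estimated correlation). Without cadmium replicate 2 both fatty acid lists turned their direction (adjusted p = 0.562 and 0.439).

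Amino acid and urea cycle genes were higher in 30 of 43 cases, cth of cysteine synthesis among them at 0.49 ± 0.09 (probes at 0.90 and 0.09). The call was up (adjusted p = 0.00822, and adjusted p = 0.592 with an estimated correlation), and it was lost without control replicate 2 (adjusted p = 0.524) and without cadmium replicate 1 (0.635). Adjusted over the list alone 3 genes passed, of which mat1a and tdo2b were higher and arg2 lower. Glycolysis and gluconeogenesis genes were higher in 29 of 40 cases, with pgam1a at 0.43, pgk1 at 0.33, pklr at 0.61 and pygl at -0.41. That call (adjusted p = 0.0437, and adjusted p = 0.575 with an estimated correlation) was lost without control replicate 2 (0.345), cadmium replicate 1 (0.195) or cadmium replicate 2 (0.132), and after scaling (0.0522) or quantile normalization (0.0543) of the arrays. Proteasome genes were higher in 34 of 41 cases, with psmc4 at 0.28, psmd9 at 0.24, psmc1a at 0.27 and the immunoproteasome activator gene psme2 at -0.63. That list was called up (adjusted p = 0.000465, and adjusted p = 0.575 with an estimated correlation), but not without control replicate 2 (0.132) or cadmium replicate 1 (0.0572).

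Oxidative phosphorylation genes were higher in 51 of 67 cases, with ndufs1 at 0.38, uqcrc2b at 0.41, atp5f1b at 0.31 and cycsb at 0.47. The call was up (adjusted p = 0.00822, and adjusted p = 0.773 with an estimated correlation). It rested on cadmium replicate 1, since without that RNA it turned to down (0.00170), without cadmium replicate 2 it was up (3.04e-29), and without control replicate 3 it was lost (0.603). Ribosomal protein genes were lower in 40 of 70 cases, with rpl36 at -0.33, rpl5a at -0.26, rpl35 at -0.16 and rpl14 at -0.20, and were not called (adjusted p = 0.0854), although they were called up without control replicate 2 (0.00742) and down without control replicate 3 (1.34e-10). Xenobiotic metabolism genes were lower in 27 of 42 cases, with cyp2k18 at -0.69 (probes at -1.37 and -0.01), cyp3c1 at -0.72, sult1st4 at -0.52 and cyp2ad2 at 0.39. The call was down (adjusted p = 0.00447, and adjusted p = 0.592 with an estimated correlation), and it was lost without control replicate 3 (0.0841) and turned without cadmium replicate 2 (0.439).

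In the clock list 17 of 30 genes were higher, 9 on all 4 arrays. Beside tefa these included the cryptochrome gene cry2 (0.37 ± 0.09), listed under its older symbol cry3, and the clock repressor gene bhlhe41 (0.44 ± 0.11). On the lower side nfil3-5, a repressor that competes with factors of the tefa family, was at -1.39 ± 0.41. The probes of cry2 were at 0.57 and 0.18, and those of bhlhe41 at 0.81 and 0.08. Without control replicate 2, nfil3-5 was at -0.82. Camera called the list up (adjusted p = 0.0469, and adjusted p = 0.575 with an estimated correlation), and the call was lost without control replicate 2 (0.241), control replicate 3 (0.173) or cadmium replicate 1 (0.748). It was also lost after scaling (0.111) or quantile normalization (0.232), with arrays as units and a dye term (0.0804), without the genes of lowest variance (0.106) and with the median over probes (0.0511). Fry, which asks whether a list's genes move on balance one way, gave its smallest adjusted p for this list (0.0772). Adjusted over the list alone, tefa passed. Growth hormone and IGF axis genes, of which 2 were also in the glucocorticoid list, were lower in 11 of 17 cases. Among the lower ones were igfbp1b (-0.41) and irs1 (-0.16), while cisha was at 0.19. The list was called down (adjusted p = 0.0437, and adjusted p = 0.592 with an estimated correlation), was lost without control replicate 3 (0.331), after scaling (0.0901) or quantile normalization (0.156) and with arrays as units and a dye term (0.05002), and turned without cadmium replicate 2 (0.342). Estrogen-responsive and vitellogenesis genes were higher in 9 of 18 cases, with nots at -0.77, fam20cl at -0.75, esr2b at -0.41 and zp3a.1 at 0.80, and were not called (adjusted p = 0.374). Without cadmium replicate 2, zp3a.1 was at -0.39, esr2b at 0.16 and fam20cl at -0.32, and without control replicate 2 nots was at -0.49. For lists whose count adjusted over the list alone is not given, it was 0.

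Markers of other tissues differed between RNAs of the same group. Ovary and oocyte markers were highest in cadmium replicate 2 in 20 of 24 cases and lowest in cadmium replicate 1 in 20, ranks that the opposite reading of the ratio would exchange. Markers lowest in cadmium replicate 2 numbered 1. This came with list medians of -0.19, -0.61, 1.41 and 1.45 on arrays 1 to 4. The egg coat gene zp3, chosen after its values were seen, was at -0.97 on array 2 and 2.58 on array 4. Cadmium against control, the germ cell genes bmp15, dazl, gdf9 and ddx4 were at 0.41 ± 0.35, 0.68 ± 0.66, 0.39 ± 0.38 and 0.33 ± 0.32. The list was called up (adjusted p = 0.0208, and adjusted p = 0.708 with an estimated correlation), without cadmium replicate 2 it was called down (5.19e-09), and without control replicate 2 (0.326) and after scaling (0.0522) or quantile normalization (0.141) it was lost. Cell cycle genes went with these markers, with medians of -0.08, -0.34, 0.86 and 0.84 and 1 shared gene. Of 36, 31 were higher with cadmium. The largest moderated t in size belonged to h2ax, which was lower (-0.51), and to uhrf1 (0.36), ccnb3 (0.22) and mcm2 (0.70), which were higher. Their call was up (adjusted p = 0.0241, and adjusted p = 0.773 with an estimated correlation), was lost without control replicate 2 (0.524) and after scaling (0.0714) or quantile normalization (0.232), and was down without cadmium replicate 2 (3.97e-09).

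**Figure D2:**
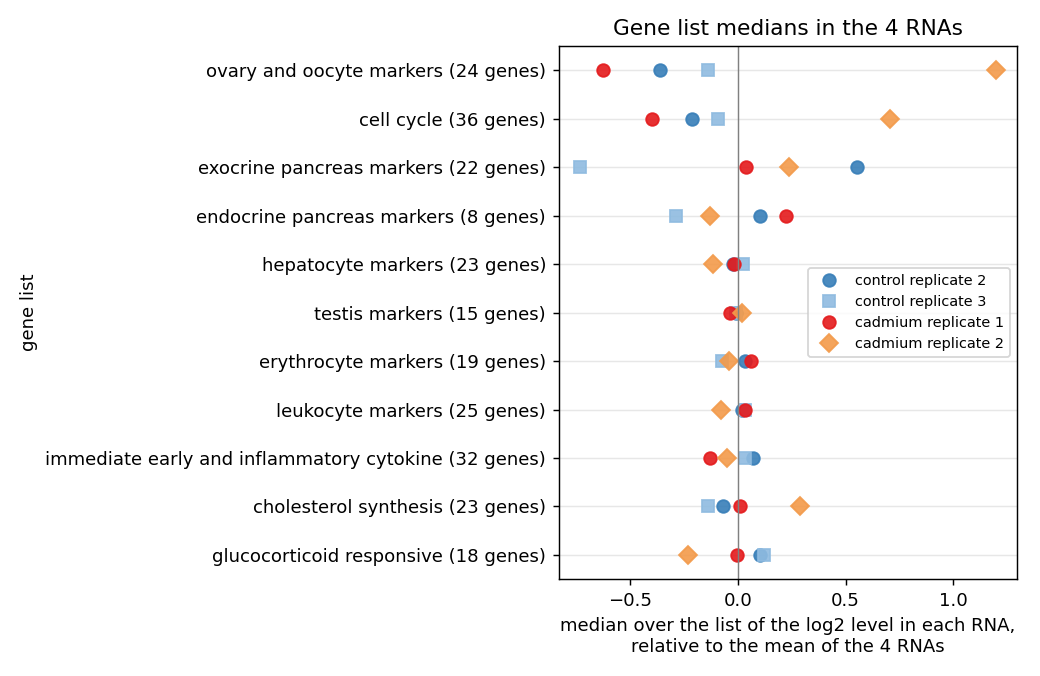
Median log2 level of 11 gene lists (vertical axis) in each of the 4 RNAs, relative to the mean of the 4 (horizontal axis), with 1 symbol per RNA. Cadmium replicate 2 stands apart for cell cycle genes (0.71) and further still for ovary and oocyte markers, and control replicate 3 has the lowest value for exocrine pancreas markers (-0.73).

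Exocrine pancreas markers were higher in control replicate 2 than in control replicate 3 in 18 of 22 cases, by a median of 1.36, and 17 were higher with cadmium (pla2g1b -0.14, cel.1 0.33, ctrl 0.68, cpa5 0.39). The list was not called (adjusted p = 0.552), but was called up without control replicate 2 (2.94e-17) and down without control replicate 3 (1.74e-14). Endocrine pancreas markers were higher with cadmium in 5 of 8 cases (gcga 0.36, insb 0.10, pdx1 -0.07, sst1.1 0.57, adjusted p = 0.682). Without control replicate 3, sst1.1 was at -0.53 and gcga at 0.02, and without cadmium replicate 2 insb was at -0.007. Hepatocyte markers were lower in 12 of 23 cases (apoeb -0.61, gc -0.37, agt -0.52, foxa3 -0.76; adjusted p = 0.188), and were called down without control replicate 3 (0.0458) or cadmium replicate 1 (0.0263).

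Leukocyte markers (19 of 25 lower, lcp1 at -0.56, ncf1 at -0.20, mpx at -0.26, coro1a at -0.19) and endothelial and stellate markers (21 of 27 lower, fli1rs at -0.27, col1a1a at -0.22, colec11 at -0.22, col1a2 at -0.25) were called down with adjusted p = 0.0241 and 0.00447, both with adjusted p = 0.592 with an estimated correlation. Both lost the call without control replicate 2 (0.132 and 0.371) and turned without cadmium replicate 2 (0.541 and 0.818), and the leukocyte list lost it after scaling (0.0522) or quantile normalization (0.0719). Skeletal muscle markers were lower in 16 of 23 cases (acta1b -0.13, casq1b 0.32, pvalb1 -0.12, myl1 -0.09) and were called down (adjusted p = 0.0480, and adjusted p = 0.592 with an estimated correlation). That call was lost without control replicate 2 (0.524) and cadmium replicate 1 (0.0627), after scaling (0.0628) or quantile normalization (0.0840) and without the genes of lowest variance (0.125), and it turned without cadmium replicate 2 (0.921). Biliary and intestinal epithelium markers (14 of 21 lower, krt8 -0.21, cdx1b -0.19, krt18a.1 -0.55, krt4 -0.24), erythrocyte markers (12 of 19 higher, hbae3 0.20, epb41b -0.41, hbae1.1 0.12, cahz -0.17) and testis markers (8 of 15 higher, tekt1 0.21, star -0.11, piwil1 0.30, spag6 -0.07) were not called (adjusted p = 0.0564, 0.987 and 0.896). The biliary and intestinal markers were called down without control replicate 3 (0.000802) or cadmium replicate 2 (0.0205), and the erythrocyte markers without control replicate 3 (0.0428). Of the 32 lists 18 were called at the preset correlation, 8 up and 10 down, and 0 with an estimated correlation or with fry.

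RNAs of one group differed widely. The difference between the 2 cadmium RNAs had a standard deviation of 0.394 over probes, with 1461 probes at least 2-fold apart. The 2 control RNAs gave 0.223 and 174 probes, and the cadmium mean minus the control mean 0.178 and 91 probes. The differences within the groups alone would give a standard deviation of 0.226 for that contrast of means, above the 0.178 observed, although array noise in this loop raises the first more than the second. Across probes, which are not independent replicates, the turned ratios of arrays 3 and 4, which share cadmium replicate 2, correlated at r = 0.66 (Spearman 0.41), and those of arrays 1 and 2, which share cadmium replicate 1, at r = 0.17 (Spearman 0.05). Arrays that share a control RNA correlated at -0.024 (arrays 1 and 4, control replicate 2) and -0.062 (arrays 2 and 3, control replicate 3), and arrays that share no RNA at -0.04 and -0.22. The dye effect had a standard deviation of 0.0946, with 0 probes called by limma and 818 at an unadjusted p under 0.05.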

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

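The comparison of 2 RNAs against 2 recovered only large differences on simulated data, and no signal over background was used to show which probes were too dim to measure. No paired analysis was possible because the control and cadmium RNAs share only 1 replicate number. No filter on missing values was needed, since 0 values were missing. The choice of array 2 alone was made after the data were seen, and it moved 86 of the 145 named genes by more than 1 SE. The causes of the differences below were not tested, except that fewer probes or a stricter threshold give fewer by construction.

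The counts of 0 genes and 0 probes were kept under centring, scaling, quantile normalization, a robust prior, the filter on lowest variance, treat and arrays as units with a dye term, for probes also under the filter to 1 symbol and for genes under the median over probes. Arrays as units without a dye term gave 3 probes and 2 genes. Leaving out 1 RNA or array gave 0 to 2523 probes and 0 to 1456 genes, the upper values without cadmium replicate 1. At an unadjusted p under 0.05, probes numbered 1832 with arrays as units, 2462 without the dye term, 439 among probes with 1 symbol, 62 with treat and 358 to 7026 with 1 RNA or array left out. Genes numbered 778, 1109, 24 with treat and 154 to 3535 on leaving out. The dye effect stayed at 0 probes under a robust prior and centring. Of the 145 named genes, 22 changed sign under at least 1 planned setting, none of them past the threshold in the setting where it turned.

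Called lists numbered 11 after scaling, 11 after quantile normalization, 0 with an estimated correlation, 0 with fry and 10 to 19 on leaving out 1 RNA or array. Scaling and quantile normalization both ended the calls of glycolysis, cell cycle, clock, growth hormone axis, leukocytes, ovary and skeletal muscle. Arrays as units ended that of the clock (0.0804 with and 0.0852 without a dye term), of the growth hormone axis (0.05002 with it) and of glycolysis (0.0581 without it). The variance filter ended those of glycolysis (0.0811), clock (0.106) and skeletal muscle (0.125), and the median over probes that of the clock (0.0511). The immediate early, cholesterol synthesis and glucocorticoid lists kept their call and direction in 16 of 18 settings and lost it with fry and the estimated correlation. Direction turned, in a called list or into a call, for 13 lists on leaving out 1 RNA or array. Their adjusted p ranged over these settings from 2.34e-05 to 0.656 for xenobiotic metabolism, 0.000632 to 0.562 for fatty acid synthesis, 3.86e-09 to 0.439 for fatty acid oxidation, 1.34e-10 to 0.891 for ribosomal proteins and 3.04e-29 to 0.955 for oxidative phosphorylation. They ranged from 1.73e-12 to 0.585 for cell cycle, 0.00176 to 0.949 for the growth hormone axis, 2.94e-17 to 0.937 for exocrine pancreas and 0.0186 to 0.976 for erythrocytes. The ranges were 0.00176 to 0.541 for leukocytes, 1.74e-05 to 0.818 for endothelium, 1.73e-12 to 0.882 for ovary and 0.0166 to 0.921 for skeletal muscle.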

Other observations

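All gene families, further genes and tests of explanations in this part were chosen after the values were seen, while the marker lists they use were fixed before. Genes of the mitochondrial ribosome (symbols starting with mrpl or mrps) were higher in the cadmium livers in 61 of 68 cases, with a median log2 difference of 0.23 and medians of 0.20, 0.27, 0.23 and 0.14 on arrays 1 to 4. Genes of the mitochondrial protein translocases were higher in 17 of 20 cases (median 0.16), a call (adjusted p = 6.85e-05, and adjusted p = 0.119 with an estimated correlation) that was lost without cadmium replicate 1 (0.120). Over 7 such families, camera gave the ribosome family an adjusted p of 1.23e-14 at the preset correlation and 0.119 with an estimated correlation, and fry gave 0.164. RNA polymerase subunits were higher in 22 of 28 cases (median 0.14), with medians of 0.05 and 0.08 on arrays 1 and 2 and of 0.32 and 0.16 on arrays 3 and 4, which hold cadmium replicate 2. Aminoacyl-tRNA synthetases were higher in 23 of 31 cases (median 0.08), with medians of 0.12, -0.04, 0.22 and 0.08 on arrays 1 to 4. Both gave an adjusted p of 0.119 with an estimated correlation, against 0.00119 and 0.00377 at the preset one, and the synthetase call was lost without cadmium replicate 1 (0.0708) or cadmium replicate 2 (0.0502). Of 13 complement components 12 were lower, 8 of them on all 4 arrays, with a median of -0.38 (adjusted p = 3.75e-11 at the preset correlation and 0.119 with an estimated correlation). Of 19 genes of interferon-linked families 5 were higher (median -0.07), and the call down (adjusted p = 0.00377, and adjusted p = 0.119 with an estimated correlation) was lost without control replicate 3 (0.217), cadmium replicate 1 (0.0708) or cadmium replicate 2 (0.0927). The egg coat genes of the zona pellucida family were higher in 17 of 17 cases (adjusted p = 0.00377, and adjusted p = 0.524 with an estimated correlation), with medians of -0.20, -0.71, 1.77 and 1.81 on arrays 1 to 4, and they were called down without cadmium replicate 2 (6.78e-14) and not called without control replicate 2 (0.160).

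Several immune genes were highest in control replicate 3 under Cy5 over Cy3, and under the opposite reading they would be lowest there. The chemotactic factor genes lect2.1 and lect2.2 were at -4.33 and -4.26 on array 2 and at -4.16 and -4.73 on array 3, which hold that RNA, and at 0.10 and -0.40 on array 1 and -1.15 and -0.78 on array 4, which do not. The complement gene c7b, the intelectin gene itln3 and the interferon-induced gene isg15 followed the same arrays, with -3.99, -2.80 and -2.11 on array 2 against -0.24, -0.66 and -0.62 on array 4. No explanation of this was tested. The low value of hamp does not rest on this RNA, since array 1 gave -2.79 and array 4 -2.32.

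Oocyte transcripts differed between the 2 cadmium RNAs, which lie on opposite sides under either direction of the ratio. An effect of cadmium shared by both is argued against by a median of -0.35 for cadmium replicate 1 minus the controls, with 3 of 24 ovary and oocyte markers higher, while cadmium replicate 2 stood 1.60 above the mean of the other RNAs. Ovary RNA in the extract of cadmium replicate 2 stays open as a candidate explanation under Cy5 over Cy3, since the 20 of 24 markers highest there are the pattern itself and no test of it, and under the opposite direction 1 marker would be highest there and 20 in cadmium replicate 1. Under Cy5 over Cy3, dilution by ovary RNA would lower all liver transcripts alike. In cadmium replicate 2 the median was -0.155 for hepatocyte markers (quartiles -0.46 and 0.13), and 54 genes were lower by at least 1 on both its arrays. The unknown normalization may have removed part of a shared drop, so this median cannot decide, and the origin of the 54 genes stays open. Apart from the ovary list, other lists ranged from -0.49 (fatty acid oxidation) to 0.94 (cell cycle). Between these lay, for example, -0.29 (acute phase), -0.01 (amino acid) and 0.39 (cholesterol synthesis). Under the opposite direction, the 249 genes higher by at least 1 on both arrays would be the lower ones. A smaller dilution stays open too, and the values at hand cannot decide it. The hepatocyte median lay below those of 10000 random lists of that size (lowest -0.146). Those lists drew genes independently, whereas the estimated correlation of the hepatocyte list was 0.056. Of the 23 hepatocyte markers, 13 were lowest in cadmium replicate 2 but 6 were highest there.

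The control RNAs differed in exocrine pancreas transcripts, for example by 2.37 for the trypsin gene prss1. Differing amounts of pancreas tissue in the dissected livers may account for this, under either direction of the ratio. If so, the endocrine markers, a separate list, should go with the exocrine ones, and 6 of 8 were higher in control replicate 2 than in control replicate 3, by a median of 0.35 against 1.36 for the exocrine list. In the cadmium RNAs, however, the exocrine median was 0.04 (replicate 1) and 0.24 (replicate 2), but the endocrine median 0.22 and -0.13. The lists went opposite ways in that pair, which limits the pancreas explanation. Tissue other than pancreas stays open beside it, since 14 of 21 biliary and intestinal markers were also higher in control replicate 2 (median 0.15), among them, picked after their values were seen, the fatty acid binding protein genes fabp6 (4.27) and fabp2 (0.80). No biological explanation was tested, as both RNAs are controls.

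The sign of the deposited ratios cannot be told apart from its opposite by the design. Genes in which 1 RNA stood at least 2 log2 units from 3 others lying within 1 unit of each other numbered 18 with the lone RNA higher and 0 with it lower, 12 of them in cadmium replicate 2 and 5 in control replicate 3. Foreign tissue or an induced response in 1 extract would give this under Cy5 over Cy3, whereas the opposite reading needs 3 extracts that share it. So few genes in 2 main RNAs leave the question open.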
